A study of Mus musculus with 3 samples.

How the data were processed

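RNA was sequenced from myeloid-derived suppressor cells (MDSCs), immature myeloid cells that restrain T cells. Per the labels' protocols, the cells were grown from mouse femur marrow for 4 days with GM-CSF and IL-6, and total RNA was used. The 3 libraries came from wild type (WT) mice, mice without the long noncoding RNA lnc57Rik (lnc57Rik KO) and mice without the long noncoding RNA lncGM1082 (lncGM1082 KO), with 1 library per genotype. The design text can be read as more than 1 sample per genotype, and whether a library pooled animals is not given in the sources used here. The growth protocol in the labels names C57BL/6 and lnc57Rik KO mice and does not name lncGM1082 KO mice.

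The values are FPKM (fragments scaled to transcript length and to the size of the library) per gene, deposited by the authors in a table with 1 column per library. Per the submitters' processing notes, Bowtie 0.12.2 and the build mm9 were used; the notes give no role or order for them. The gene positions in the table follow another build. Of 20649 rows with an Ensembl identifier, 20607 were found in GENCODE M21 on GRCm38, and 19553 of these had the identical chromosome, strand, start and end there. Coordinates are therefore given on GRCm38. The counting software, its strand setting and the treatment of reads that fit several genes are not given in the sources used here. Genes with near-identical copies (Hspa1a and Hspa1b, the H2-Q genes, histones, Ear and Stfa genes, ribosomal protein genes and pseudogenes) and genes with an overlapping or antisense partner are uncertain for that reason.

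The table holds 57561 rows, of which 36912 carry a NONCODE identifier for long noncoding RNA. Low FPKM values were whole multiples of the value of 1 fragment. With the summed exon lengths of GENCODE M21, 99.1% of values under 20 fragments came out whole within 0.05 fragments for genes with 1 transcript, and 93.4% for genes with several, where 10% would do so by chance. The fragment total behind the FPKM was 18485061 for WT, 17593399 for the lnc57Rik KO and 18280526 for the lncGM1082 KO library. In a gene of 1000 exon bases, 1 fragment was worth 0.0541, 0.0568 and 0.0547 FPKM in that order. These fragments were used for intervals of FPKM ratios only, at a level of 95%, from the exact (Clopper-Pearson) binomial interval of the fragments of both libraries. Fragments are not independent molecules, so the intervals cover counting error only, without differences between mice, cultures or library preparations. A value of 0 was given an upper limit of 3 fragments.

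Folds were taken as the log2 ratio of FPKM after adding a pseudocount of 1, which understates the change of low genes. Rows with a mean FPKM of at least 1 over the 3 libraries were compared, 22202 in all, of which 12041 were Ensembl and 10161 NONCODE rows. With 1 library per genotype there is no replicate check and no test. A gene was called higher or lower by a rule of size, an absolute log2 fold of at least 1. No p-value is given, since genes are not replicates.

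The gene lists were fixed before the data were examined. They cover suppressive effectors, C/EBP and other myeloid transcription factors, GM-CSF and IL-6 targets, interferon response, inflammatory cytokines and chemokines, inflammasome, cell cycle, glycolysis and hypoxia, oxidative phosphorylation, cholesterol synthesis, lipid uptake and efflux, ER stress, antigen presentation, toll-like receptor signalling, and phagocytic and Fc receptors. Cell type lists cover primary granules, secondary and tertiary granules and mature markers of neutrophils, monocytes and macrophages, dendritic cells, eosinophils, basophils and mast cells, lymphoid cells, erythroid cells, megakaryocytes, stem and progenitor cells, and stromal and endothelial cells. Lists for sample quality hold ribosomal protein, mitochondrially encoded, immediate early and heat shock, replication-dependent histone, sex-specific and C57BL/6 substrain genes. The median log2 fold of a list's members with a mean of at least 1 FPKM was placed among 10000 random lists of the same size, matched on mean FPKM in 20 bins. A list with under 5 such members got no percentile. A list is said to stand outside the random lists below percentile 2.5 or above 97.5, which 5% of lists of unrelated genes would do by chance. Members of the fixed lists can move together, and some lists share members, so more of them may stand outside without an effect of the genotype. This describes these libraries and is not a test of the genotype.

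Named genes followed a rule fixed before the data were examined: the targeted transcripts; per comparison the 10 genes with the largest positive and the 10 with the largest negative fold among genes with a mean of at least 5 FPKM; and up to 4 members with the largest absolute fold from each list that stood outside the random lists or had at least 3 members past the rule of size. Clone and predicted names, small RNAs and antigen receptor segments were left out of the largest folds. Arg1, Nos2, Ptgs2 and Cybb were named whatever their values. A symbol on several rows was represented by the row with the highest mean. Not every gene that the rule names is given in the text. Genes named outside the rule are said to have been chosen after their values were seen.

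Both knockouts were compared with the same WT library, so overlaps and correlations between those comparisons lie above 0 without any effect. Unchanged libraries were simulated 20 times from the mean FPKM and the fragment totals, with counting error alone and with an added coefficient of variation of 0.1 or 0.2 per gene. The alternatives tried were other pseudocounts, filters, scalings, sizes of fold, and summing of rows with the same symbol.

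The steps were tested on simulated data. In 20607 simulated genes of which 200 were changed, the rule of size recovered 15 of 100 genes changed 2-fold and 83 of 100 changed 4-fold for lnc57Rik KO against WT. For lncGM1082 KO against WT it recovered 21 and 87 of 100, and for lncGM1082 KO against lnc57Rik KO 13 and 88 of 100. Of unchanged simulated genes, 0.516%, 0.516% and 0.633% passed it in that order. These simulated libraries differed by counting error only, without variation between mice, cultures or preparations. The shares are therefore not rates of false calls in the real comparisons. Of 200 random lists of 20 genes with no shift, 4%, 2.5% and 5% stood outside in the 3 comparisons. Genes were drawn at random there, so lists of genes that move together were not covered. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.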

Results

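Gene expression was measured by RNA sequencing in MDSCs cultured from the marrow of WT, lnc57Rik KO and lncGM1082 KO mice, with 1 library per genotype. The values rest on 18485061, 17593399 and 18280526 fragments in that order. Ferritin heavy chain (Fth1) alone took 6.09% of summed FPKM in WT, 3.93% in the lnc57Rik KO and 5.76% in the lncGM1082 KO library. No difference given here has a replicate check, and the intervals cover counting error only. The sex-specific genes with at least 1 FPKM, which were Y-linked, had a median log2 fold of 0.00 in the lnc57Rik KO and -0.03 in the lncGM1082 KO library against WT.

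The targeted transcripts were examined first. The name Gm1082 is a RefSeq synonym of Arhgap33os, an antisense long noncoding RNA gene on the plus strand of chromosome 7 from 30515122 to 30522193 (GRCm38), beside Arhgap33. A NONCODE row at the identical position held 1 fragment in WT (0.0204 FPKM), 0 in the lnc57Rik KO and 3 in the lncGM1082 KO library (0.0620 FPKM). The 0 allows up to 0.0644 FPKM. The FPKM ratio of lncGM1082 KO to WT was 3.03, with a 95% interval from 0.244 to 159, so a loss of this transcript was not detectable at this depth and the row does not check the label. No row was matched to lnc57Rik, because 0 symbols end in 57Rik, and no value is given for it.

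The first comparison asked how MDSCs without lnc57Rik differ from WT. In the lnc57Rik KO library, genes of the B lineage were far higher, and Arg1 and Nos2, enzymes that deplete arginine and make nitric oxide, were lower. Cd79b, a signalling chain of the B cell receptor, had 2.19 FPKM in WT and 53.5 in the lnc57Rik KO library, a ratio of 24.4 (95% interval 18.8 to 32.3). Arg1 went from 626 to 262 FPKM, a ratio of 0.418 (0.409 to 0.428), and Nos2 from 886 to 426 FPKM, a ratio of 0.480 (0.474 to 0.487). Cell cycle, histone, interferon and antigen presentation genes were higher as groups, and markers of mature neutrophils were lower.

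Of 22202 rows compared, 752 were higher and 340 lower by the rule of size, and among Ensembl rows 456 and 168. The counts over all rows ranged from 179 and 46 with a pseudocount of 5 to 2335 and 1335 when each library was scaled to a larger fixed sum without its top 20 rows. Of 623 genes past the rule of size with known fragments, 546 had a 95% interval of the ratio that excluded 1. A large ratio was the ground for choosing them, so this share is no separate support. Of 68 named genes past the rule, 20 no longer passed it with a pseudocount of 5 and 3 under median ratio scaling, and 0 changed direction. The median log2 fold of all rows was 0.07. Of 29 lists with a percentile, 17 stood outside the random lists, 11 above and 6 below. Lists of unrelated genes would give 1.45, but members of these lists can move together, so 1.45 is too low a measure of chance. Between 16 and 19 lists stood outside over the settings.

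Lymphoid markers had a median log2 fold of 2.27 over 12 members, of which 9 were higher. The filter takes the mean over all 3 libraries, so some members passed it only through the lnc57Rik KO library. Vpreb3 had 0.126 FPKM in WT and 7.54 in the lnc57Rik KO library. The filter thus favours a high median here. The median depended on the setting, with 0.87 without the filter on mean FPKM, 0.89 with a pseudocount of 5 and 3.95 with 0.1. Among them were Cd79b at 4.09, the receptor chain Cd79a at 3.34 and Vpreb3, a pre-B cell gene, at 2.92. Other genes with large folds included Ly6d, a surface protein of early B cells (4.09), Fcmr, the receptor for IgM (3.62), Pou2af1, a B cell coactivator (3.56), Spib, a transcription factor of B cells and plasmacytoid dendritic cells (3.40), Cd72 (2.72) and Cd22 (2.62). Serpina3f, a serine protease inhibitor, had a log2 fold of 3.16. With a pseudocount of 5 the folds of Vpreb3 (to 1.29), Fcmr, Pou2af1, Cd72, Cd22 and Serpina3f shrank by over 1.5 times and stayed past the rule of size, and with 0.1 that of Vpreb3 was 5.08.

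Dendritic cell markers had a median of 0.76, with 8 of 20 higher and 1 lower. Among them were Cd83 (2.48), the class II transactivator Ciita (2.38), the actin-bundling protein Fscn1 (2.09) and the chemokine Ccl22 (1.95), which stood at 70.1 FPKM in WT and 274 in the lnc57Rik KO library. Antigen presentation genes had a median of 0.66 with 4 of 17 higher. Besides Ciita these were the immunoproteasome subunit Psmb9 (1.46), the class I transactivator Nlrc5 (1.37) and the peptide transporter Tap1 (1.24). Interferon response genes had a median of 0.59, and 29 of 29 had a fold above 0, of which 4 passed the rule of size. These were the guanylate-binding proteins Gbp2, from 17.4 to 103 FPKM, and Gbp3 (1.31), Ifit3 (1.42) and Ifi44 (1.31). With a pseudocount of 5 the fold of Ciita was 1.47, and Ifi44 (0.54) and Gbp3 (0.98) no longer passed the rule; with 0.1 that of Ifi44 was 2.02. B cells express class II genes as well, and the B lineage genes were higher in the same library.

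Cell cycle genes had a median of 0.74. Of 30 members, 30 were above 0 and 5 passed the rule of size, with Mcm6 (1.23), Mcm7 (1.16), Mcm5 (1.09) and Mcm2 (1.07), subunits of the replicative helicase, as the largest. Replication-dependent histones had a median of 1.31 with 8 of 14 higher, led by Hist1h2ae at 2.13, though their reads may be shared between copies. Eosinophil markers had a median of 1.09 with 6 of 10 higher, among them the ribonucleases Ear2 (1.40) and Ear1 (1.35), which are near-identical copies, the transcription factor Gata1 (1.23) and the chemokine receptor Ccr3 (1.17). Basophil and mast cell markers had a median of 0.74 with 3 of 11 higher, which were Cpa3 (1.40), Prss34 (1.13) and Mcpt8 (1.05), all proteases. Stem and progenitor markers had a median of 0.56 with 0 of 7 higher, which was 0.11 without the filter and 0.33 with a pseudocount of 5. With that pseudocount the medians of eosinophil markers and of basophil and mast cell markers were 0.63 and 0.39. ER stress genes had a median of 0.49 with 2 of 20 higher, Psat1 of serine synthesis (1.10) and the chaperone partner Sdf2l1 (1.09). Lipid uptake and efflux genes had a median of 0.23, barely above the random lists, with the sterol exporter Abcg1 higher (1.01), and the median was 0.14 under median ratio scaling. With a pseudocount of 5 Ccr3 (0.66), Gata1 (0.52), Cpa3 (0.89), Mcpt8, Psat1, Abcg1 and the 4 Mcm genes above no longer passed the rule of size. Under median ratio scaling Mcm2, Mcpt8 and Abcg1 did not pass it either.

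Mature neutrophil markers had a median of -0.68, and 6 of 20 were lower. Ly6g, the surface marker of mouse neutrophils, went from 73.4 to 21.1 FPKM (log2 fold -1.75). Retnlg (-1.74) and the chemokine receptor Cxcr2 (-1.44) were lower too. Immediate early and heat shock genes had a median of -0.52 with 2 of 17 lower, Fosb (-1.22) and Hspa1a (-1.21). Monocyte and macrophage markers had a median of -0.24, with 2 of 21 higher and 4 lower. The lower members included fibronectin (Fn1, -2.13), versican (Vcan, -1.37) and the transglutaminase subunit F13a1 (-1.09), and the complement gene C1qb was higher (1.44). Phagocytic and Fc receptors had a median of -0.27 with 1 of 18 higher, the scavenger receptor Marco (1.13). Glycolysis and hypoxia genes had a median of -0.22 with 0 of 24 past the rule of size, and toll-like receptor genes -0.13 with Tlr9 higher (1.80). The toll-like receptor median lay between -0.20 and -0.07 over the settings, and the monocyte and macrophage median between -0.41 and -0.16. With a pseudocount of 5 C1qb (0.75), F13a1, Fosb and Marco no longer passed the rule of size.

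The largest negative folds were in Steap4, a metalloreductase (-3.18), Olfml2b (-2.56), the secreted prokineticin Prok2 (-2.40), Fn1, the acute phase protein Saa3 (-1.87), the pseudogene Rps13-ps2 (-1.81) and the carbonic anhydrase Car4 (-1.80). Steap4 had 24.3 FPKM in WT and 1.80 in the lnc57Rik KO library, and its fold shrank by over 1.5 times with a pseudocount of 5. Suppressive effectors as a list lay within the random lists, with a median of -0.15 at percentile 5.77. The 3 lower members of 24 were Mmp9, a gelatinase (-1.49), Arg1 (-1.25) and Nos2 (-1.06). Ptgs2, the inducible prostaglandin synthase, had a log2 fold of 0.18 and Cybb, the NADPH oxidase subunit, -0.10, both small folds that moved by over 1.5 times under median ratio scaling. On GRCm38, Arg1 lies on chromosome 10 from 24915221 to 24927484 and Nos2 on chromosome 11 from 78920787 to 78960254.

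The remaining lists with a percentile lay within the random lists. Their medians were -0.12 for secondary and tertiary neutrophil granules, -0.11 for GM-CSF and IL-6 targets, -0.11 for the inflammasome, -0.05 for inflammatory cytokines and chemokines, -0.03 for C/EBP and myeloid transcription factors and -0.02 for ribosomal proteins. They were 0.06 for megakaryocyte markers, 0.09 for cholesterol synthesis, 0.10 for oxidative phosphorylation, 0.12 for primary granules and 0.22 for mitochondrially encoded genes. Of 16 secondary and tertiary granule genes 3 were lower by the rule of size, and the mean log2 fold of that list was -0.34. Of 25 inflammatory cytokines and chemokines 4 were higher, among them Ccl24 (1.95), Il12b (1.67) and Ccl7 (1.20), and 14 were below 0. With a pseudocount of 5 Il12b (0.93) and Ccl7 (0.70) no longer passed the rule. Without a percentile, the median was 0.74 over 3 erythroid markers, -0.20 over 3 stromal and endothelial markers and 0.64 over 2 substrain genes.

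**Figure D1:**
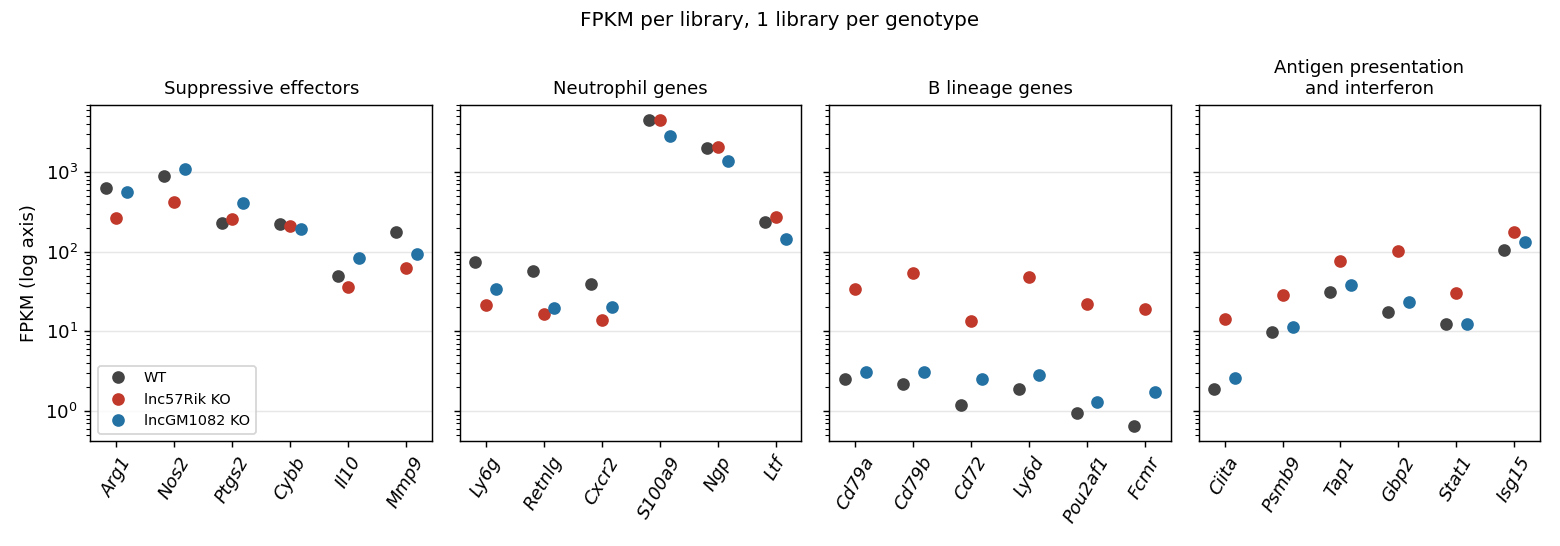
FPKM on a log axis of chosen genes in each library, in 4 groups of genes, with 1 point per library (1 library per genotype) and no error bars. Cd79b stands at 53.5 FPKM in the lnc57Rik KO library against 2.19 in WT, and Arg1 at 262 against 626.

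The second comparison asked how MDSCs without lncGM1082 differ from WT. Fewer genes passed the rule of size, and the largest positive folds were in the inducible heat shock proteins Hspa1a and Hspa1b. Hspa1a stood at 54.7 FPKM in WT and 299 in the lncGM1082 KO library, a ratio of 5.46 (95% interval 5.25 to 5.68), and Hspa1b at 22.4 and 108 FPKM, a ratio of 4.80 (4.51 to 5.12). They are near-identical copies on chromosome 17. Secondary and tertiary neutrophil granule genes and mature neutrophil markers were lower as groups, and primary granule genes were not. Arg1 and Nos2 did not pass the rule of size, with 569 and 1087 FPKM and log2 folds of -0.14 and 0.29.

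By the rule of size 192 of 22202 rows were higher and 210 lower, and among Ensembl rows 106 and 126. The counts over all rows ranged from 23 and 18 with a pseudocount of 5, where more genes were higher than lower, to 1180 and 1074 under the scaling without the top 20 rows. Of 232 genes past the rule of size with known fragments, 158 had a 95% interval that excluded 1, again among genes chosen for a large ratio. The median log2 fold of all rows was 0.01. Of 29 lists, 14 stood outside the random lists, 9 above and 5 below, though few of their members passed the rule of size. The 14 became 11 with a minimum mean of 5 FPKM and 12 without the filter.

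After Hspa1a (log2 fold 2.43) and Hspa1b (2.21), the largest positive folds were in the nonclassical class I genes H2-Q6 (1.35), H2-Q4 (1.22) and H2-Q5 (1.14), which are near-identical copies, in the autophagy gene Atg2a (1.21), and in Ccr7, the lymph node homing receptor (1.12). They were followed by Ccrl2 (1.10), the calcium channel subunit Cacnb3 (1.06) and Sema7a (1.02). Inflammatory cytokines and chemokines had a median of 0.27 with 1 of 25 higher, the interleukin subunit Il12b (1.02), and with Cxcl1 (0.89) and Ccl5 (0.89) below the rule of size. Against WT, Il12b was higher still in the lnc57Rik KO library (1.67). Dendritic cell markers had a median of 0.12 with Ccr7 as the higher member of 20, and the median lay between 0.04 and 0.21 over the settings. ER stress genes had a median of 0.21, and their largest folds were Ppp1r15a (0.88) and Ddit4 (0.74). Ptgs2 had 227 FPKM in WT and 411 in the lncGM1082 KO library, with a log2 fold of 0.86, and Cybb had a log2 fold of -0.20.

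With 0 members past the rule of size, 6 other lists stood above the random lists. Their medians were 0.30 for eosinophil markers, 0.29 for histones, 0.22 for basophil and mast cell markers, 0.17 for interferon response, 0.17 for lymphoid markers and 0.13 for primary granules. Lymphoid markers included Cd79b at 0.35, with 2.19 FPKM in WT and 3.06 in the lncGM1082 KO library, which was 0.16 with a pseudocount of 5. Some lymphoid members passed the filter only through the lnc57Rik KO library and were near 0 in both libraries compared here. Vpreb3 had 0.126 FPKM in WT and 0.0637 in the lncGM1082 KO library. Over the settings the lymphoid median lay between 0.04 and 0.43, and that of basophil and mast cell markers was 0.09 with a minimum mean of 5 FPKM. The primary granule median was 0.09 without the filter.

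Mature neutrophil markers had a median of -0.51, and 3 of 20 were lower. They were Retnlg (-1.49), the cystatin-like gene BC100530 (-1.17) and Ly6g (-1.09). Secondary and tertiary granule genes had a median of -0.39 with 0 of 16 past the rule of size, and 15 were below 0. Their mean log2 fold was -0.40, against -0.34 in the lnc57Rik KO library. Their largest folds were Mmp9 (-0.90), the chitinase-like Chil3 (-0.73), lactoferrin (Ltf, -0.71) and the granule protein Ngp (-0.57), which went from 2025 to 1368 FPKM. Ribosomal protein genes had a median of -0.22 with 24 of 24 below 0, and cholesterol synthesis genes a median of -0.22 with 20 of 20 below 0, among them Hmgcs1 at -0.34. Oxidative phosphorylation genes had a median of -0.09. The largest negative folds were in the pseudogene Rps13-ps2 (-3.08), Rps18-ps3 (-1.59), Fosb (-1.56), Retnlg, Fn1 (-1.38), the ribosomal protein Rps27a (-1.27), lysozyme (Lyz2, -1.24), Ly6g, Car4 (-1.04) and Steap4 (-1.03). With a pseudocount of 5 the folds of Cacnb3, Il12b, Fosb and Rps18-ps3 shrank by over 1.5 times. Of 22 named genes past the rule of size, 6 no longer passed it there, Cacnb3, Il12b, Sema7a, BC100530, Rps18-ps3 and Steap4, and 0 changed direction. Reads of ribosomal pseudogenes may be shared with their parent genes, which was not tested.

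The other lists lay within the random lists. Their medians were -0.10 for phagocytic and Fc receptors, -0.07 for suppressive effectors, -0.05 for GM-CSF and IL-6 targets, -0.05 for immediate early and heat shock genes, -0.03 for lipid uptake and efflux, -0.03 for cell cycle, -0.02 for the inflammasome, -0.01 for monocyte and macrophage markers and -0.01 for antigen presentation. They were 0.00 for C/EBP and myeloid transcription factors, 0.04 for toll-like receptor signalling, 0.04 for mitochondrially encoded genes, 0.06 for glycolysis and hypoxia, 0.08 for stem and progenitor markers and 0.17 for megakaryocyte markers. Without a percentile, the median was 0.35 for erythroid, 0.12 for stromal and endothelial and 0.12 for substrain genes.

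**Figure D2:**
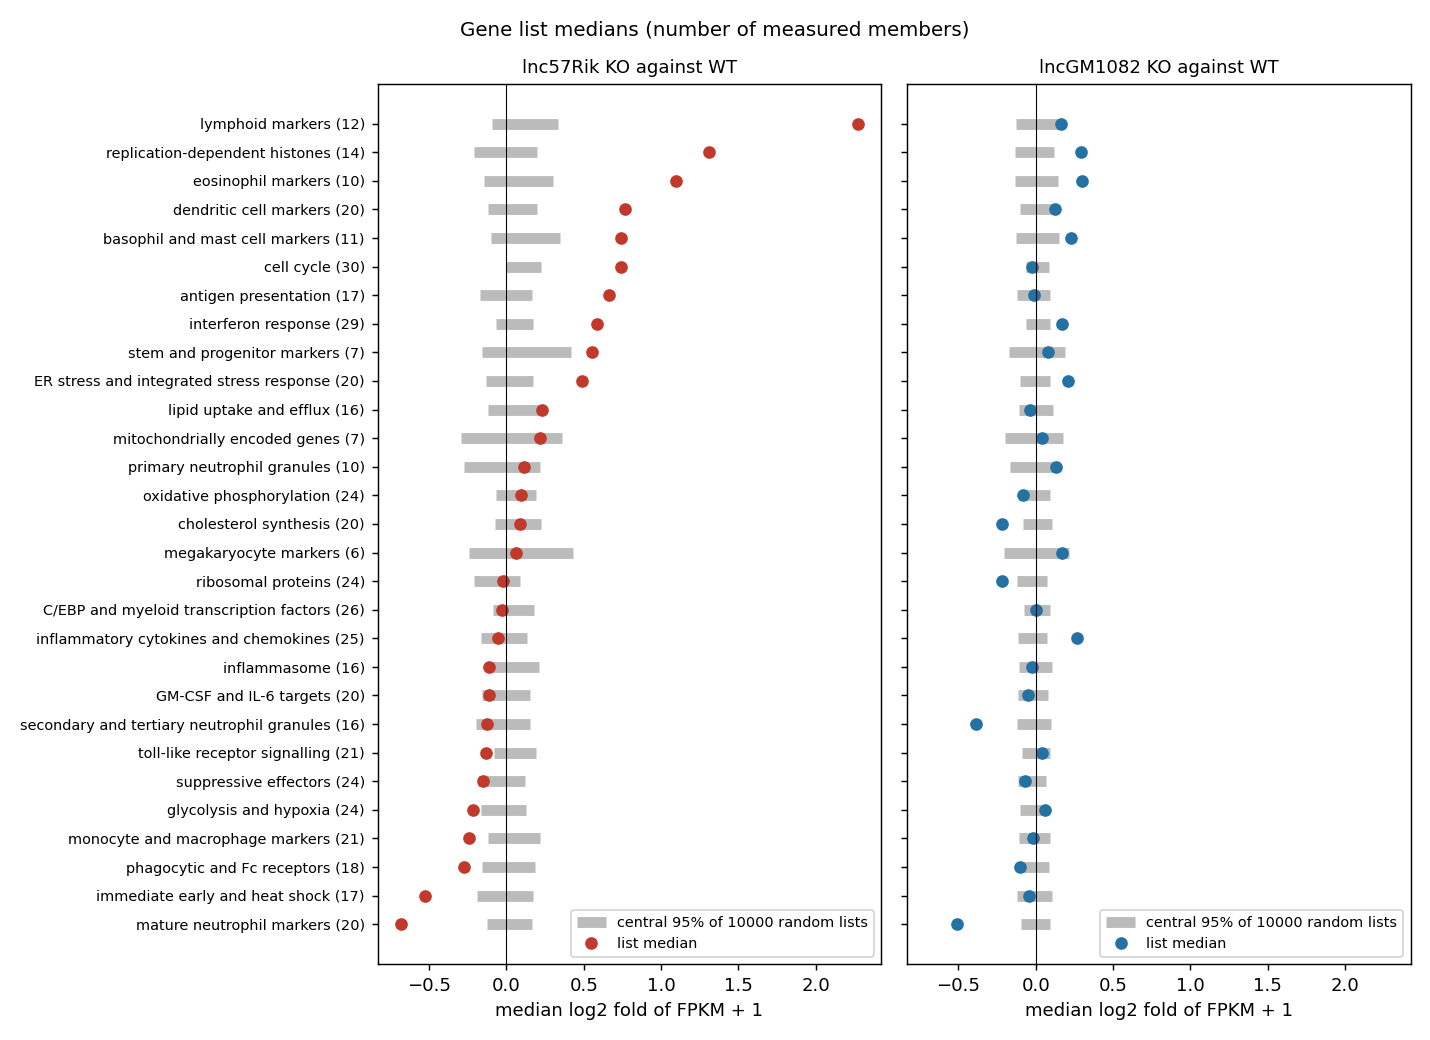
Median log2 fold of FPKM + 1 of each gene list with at least 5 measured members, for lnc57Rik KO against WT and lncGM1082 KO against WT; points are list medians and grey bars the central 95% of 10000 matched random lists. Lymphoid markers stand at 2.27 in the lnc57Rik KO and 0.17 in the lncGM1082 KO library, and mature neutrophil markers at -0.68 and -0.51. Without the filter on mean FPKM, which is not drawn, the lymphoid medians were 0.87 and 0.07.

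The third comparison set the 2 knockouts against each other and asked where they differ. Against the lnc57Rik KO library, the lncGM1082 KO library had far less B lineage RNA and more Arg1, Nos2 and Il10. Arg1 had a log2 fold of 1.12, Nos2 of 1.35 and the cytokine Il10 of 1.18, with 83.0 FPKM against 36.0. By the rule of size 290 rows were higher and 681 lower, with a range from 40 and 142 under a pseudocount of 5 to 1353 and 2186 under the scaling without the top 20 rows. Of 544 genes past the rule with known fragments, 468 had an interval that excluded 1, again among genes chosen for a large ratio. Of 29 lists, 21 stood outside the random lists, 7 above and 14 below. The 21 became 18 with a minimum mean of 5 FPKM and 19 without the filter.

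Lymphoid markers had a median of -2.11 with 9 of 12 lower, among them Cd79b (-3.75), Cd79a (-3.10) and Vpreb3 (-3.01). The median was -0.79 without the filter, -0.85 with a pseudocount of 5 and -3.46 with 0.1. Outside that list, Ly6d (-3.70), Pou2af1 (-3.30), Fcmr (-2.89) and the class II chaperone subunit H2-DMb2 (-2.54) were lower as well, and the folds of Vpreb3 (to -1.31), Pou2af1 and Fcmr shrank by over 1.5 times with a pseudocount of 5. That of Vpreb3 was -5.55 with 0.1. Of 53 named genes past the rule of size, 16 no longer passed it with a pseudocount of 5 and 1 under median ratio scaling, and 0 changed direction. Histones had a median of -0.999 with 7 of 14 lower, antigen presentation genes -0.87 with 6 of 17, dendritic cell markers -0.85 with 7 of 20, cell cycle genes -0.79 with 9 of 30 and eosinophil markers -0.56 with 3 of 10. Basophil and mast cell markers had a median of -0.55, stem and progenitor markers -0.41, interferon response -0.40, secondary granules -0.34, cholesterol synthesis -0.28, lipid uptake and efflux -0.24, ER stress -0.23 and ribosomal proteins -0.20. The mean of the secondary and tertiary granule list was only -0.06, with 1 of 16 members higher. The stem and progenitor median was -0.18 without the filter, that of basophil and mast cell markers -0.30 with a pseudocount of 5, and that of ribosomal proteins -0.12 under median ratio scaling.

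The lists above the random lists were inflammatory cytokines and chemokines (median 0.28), glycolysis and hypoxia (0.27), suppressive effectors (0.25), toll-like receptor signalling (0.19), mature neutrophil markers (0.18), phagocytic and Fc receptors (0.16) and monocyte and macrophage markers (0.15). In suppressive effectors 3 of 24 members were higher, Nos2, Il10 and Arg1. The glycolytic regulator Pfkfb3 was higher (1.20). Hspa1a (3.64), Hspa1b (3.14), Olfml2b (2.17), Steap4 (2.15), Prok2 (1.91), Orm1 (1.58), Gja1 (1.43) and Asprv1 (1.39) had the largest positive folds next to Atg2a (1.36) and Nos2, and that of Steap4 shrank by over 1.5 times with a pseudocount of 5.

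Some genes went the same way in both knockouts against WT. By the rule of size 76 rows were higher in both and 51 lower in both, 127 in all, and 8 went opposite ways, where independent lists would share 6.50 and 3.22. The 127 became 18 with a log2 fold of at least 1.5, 19 with a pseudocount of 5, 443 with 0.1 and 869 under the scaling without the top 20 rows. That scaling also raised the level of all values, and at the deposited level it gave 129. Ccr7, H2-Q6 and Il12b were higher in both. Ly6g, Retnlg, Fn1, Car4, Steap4, Lyz2, Fosb and the pseudogene Rps13-ps2 were lower in both. With a pseudocount of 5, Steap4 did not pass the rule in the lncGM1082 KO library. Fosb did not pass it there in the lnc57Rik KO library, and Il12b passed it in neither. On 12028 Ensembl rows, 88 went the same way, against 14.1 in simulated unchanged libraries with counting error alone, 16.2 with an added coefficient of variation of 0.1 and 34.0 with 0.2. Part of the excess may come from the shared WT library, which cannot be split.

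Across genes, which are not independent replicates, the log2 folds of both knockouts had a Pearson's r of 0.39 and a Spearman's rho of 0.37 over 22202 rows. On the 12028 Ensembl rows r was 0.39, and simulated unchanged libraries gave 0.49 with counting error alone. The covariance there was 0.0595, against 0.0150 simulated with counting error alone, 0.0297 with a coefficient of variation of 0.1 and 0.0745 with 0.2. The observed covariance thus lay above or below the simulated one according to the variation between libraries, which 1 library per genotype does not give.

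**Figure D3:**
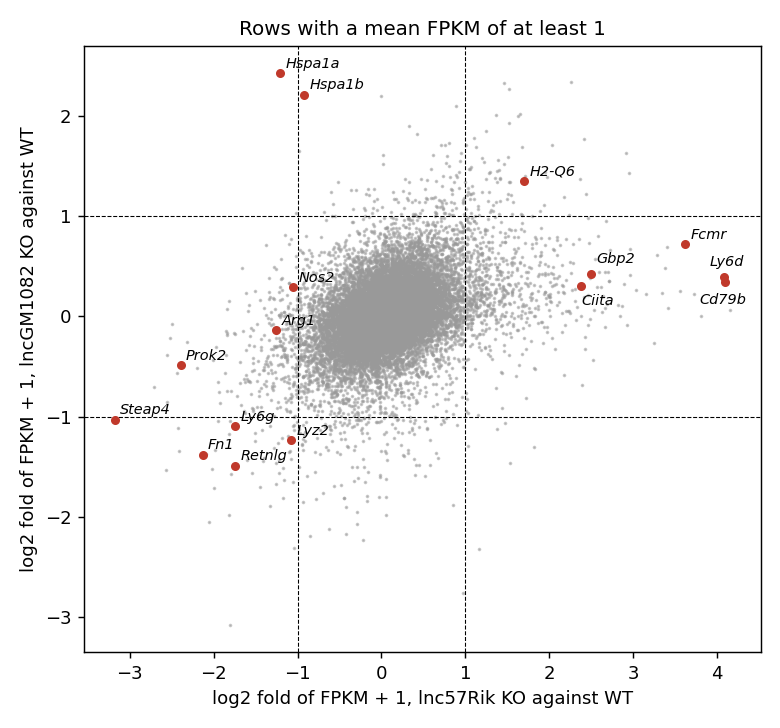
Log2 fold of FPKM + 1 of lnc57Rik KO against WT (horizontal axis) and lncGM1082 KO against WT (vertical axis) for 22202 rows, 1 grey point each, with 16 genes marked in red and dashed lines at the rule of size. Cd79b and Ly6d lie far to the right at 4.09, and Hspa1a lies at the top at 2.43.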

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

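No paired analysis was possible because there is 1 library per genotype, and for the same reason no library could be left out. The choice of Ensembl rows only and scaling to equal sums at the deposited level were chosen after seeing the data. Of 416 alternative values of the 52 list medians outside the random lists and 1656 of the named genes' folds, 0 called values changed sign. Of the list medians, 78 moved by more than the standard deviation of the random lists' medians. Of the folds, 270 moved by more than the distance from the middle to the end of their counting interval in log2. Folds without a finite interval were counted among the 270. The correlation stayed between 0.39 and 0.41 under the alternatives run. Counts are given as higher and lower for lnc57Rik KO against WT, then lncGM1082 KO against WT, then lncGM1082 KO against lnc57Rik KO, then genes going the same way in both knockouts. As reported they were 752 and 340, 192 and 210, 290 and 681, and 127. With a pseudocount of 0.1 they were 1397 and 722, 570 and 520, 707 and 1273, and 443; with 5 they were 179 and 46, 23 and 18, 40 and 142, and 19. With a minimum mean of 5 FPKM, which leaves fewer genes, they were 234 and 122, 57 and 40, 112 and 200, and 38. With a log2 fold of at least 1.5 they were 287 and 80, 37 and 54, 64 and 250, and 18. On Ensembl rows only, which are fewer, they were 456 and 168, 106 and 126, and 141 and 404. Scaled to a fixed sum above the deposited ones they were 2164 and 1047, 978 and 860, 1093 and 1926, and 698, and without the top 20 rows 2335 and 1335, 1180 and 1074, 1353 and 2186, and 869. That scaling also multiplies every value, so the pseudocount and the filter weigh less: scaled to equal sums at the deposited level the counts were 774 and 317, 206 and 198, 303 and 672, and 132. Without the top 20 rows at that level they were 726 and 358, 196 and 210, 315 and 643, and 129. Median ratio scaling, no filter and summed rows kept the counts within 1.5 times. For lncGM1082 KO against WT, which of higher or lower was more frequent changed with the setting. Depth limits genes of few fragments, among them the targeted transcript at 1 and 3 fragments.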

Other observations

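The tests on myeloid genes, mature neutrophils and scaling for Arg1 and Nos2, and those on shared reads and immediate early genes for Hspa1a and Hspa1b, were chosen after the results were seen. The lists of B cell, T and NK cell, plasma cell and chaperone genes were written after the folds of the fixed lists were seen and before these genes' own values were read. Those lists were first computed with a minimum mean of 0.2 FPKM, which no plan had named; the values below use the minimum of 1 FPKM of the fixed lists, and the first values are given beside them where they differ. A bound was taken as passed only where the median lay beyond it by more than its bootstrap spread over members, a condition added after the first values were seen.

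The immunoglobulin heavy chain genes Ighm and Ighd, chosen after their values were seen, followed the B lineage genes. Igha and Ighg2c were looked up as well, and their values are not given here. Ighm stood at 6.97 FPKM in WT, 141 in the lnc57Rik KO and 7.31 in the lncGM1082 KO library, and Ighd at 2.36, 34.9 and 2.56. Plasma cell genes (Jchain and others) did not follow, with a median log2 fold of 0.13 over 6 genes in the lnc57Rik KO and -0.10 in the lncGM1082 KO library (0.15 and -0.04 over 7 genes with the minimum of 0.2). Cebpb, a transcription factor of MDSC differentiation also chosen after its values were seen, stood at 236 FPKM in WT, 150.1 in the lnc57Rik KO and 148 in the lncGM1082 KO library. It passed the rule of size in neither knockout, and both comparisons share the WT library. Its fixed list lay within the random lists, with medians of -0.03 and 0.00 in that order.

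B lineage genes were higher in the lnc57Rik KO library. A candidate explanation is that more B cells remained among the cultured cells, and the labels name no sort that would remove them. B cell genes not looked at before had a median log2 fold of 2.05 over 14 genes, of which 11 were higher (1.46 over 17 genes with the minimum of 0.2), which is consistent with it; 6 of them also had at least 1 FPKM in WT. Lymphocytes of every kind remain open, since T and NK cell genes had a median of 0.60 over only 4 genes, between the bounds set (0.38 over 12 genes with the minimum of 0.2, which lay below the bound of 0.5 by less than its spread). With no minimum the median was 0.38 over 14 genes and lay below that bound by slightly more than its spread of 0.114, but only 2 of them had at least 1 FPKM in WT, and the pseudocount holds the folds of such low genes near 0. An effect of the genotype on B cells, or a difference between cultures, was not separated with 1 library each.

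Arg1 and Nos2 were lower in the lnc57Rik KO library. Fewer myeloid cells as the whole cause could not be measured directly. Over 44 myeloid receptor and granule genes the median log2 fold was -0.11, far from the fold of Arg1 and Nos2. This argued against a fall of that size across these genes. The medians of the pooled lists had been seen before, and not all members are particular to myeloid cells. Monocyte and macrophage markers were not pooled with them. Their median was -0.24, below the random lists, with 4 of 21 lower and 2 higher. Fewer monocytic cells as a cause was not tested. The weaker of both folds stayed at -1.03 or beyond under 3 scalings. These shifted the lnc57Rik KO library against WT by log2 values of only -0.09, 0.02 and -0.02. The 3 scalings therefore do not account for the folds, and a larger error of scaling was not tested. Fewer mature neutrophils cannot be told apart from a change within cells, since mature neutrophil markers had a median of -0.68, between the bounds. These markers were also lower in the lncGM1082 KO library, with a median of -0.51, where Arg1 and Nos2 did not pass the rule of size. That is 1 library of another genotype, so it does not settle the question. A lower expression of both genes in MDSCs without lnc57Rik is a hypothesis that may be followed up with replicates.

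Hspa1a and Hspa1b were higher in the lncGM1082 KO library. A different split of reads between the copies would raise a copy and lower the other, and was argued against by the rise of both. The log2 fold of their sum, 2.38, follows from that rise and is no separate evidence. An immediate early response during handling above that of the WT library was argued against by a median of -0.11 over 13 immediate early genes. Its spread was 0.234. Whether the WT library itself stood high was not tested. The fixed list, which includes heat shock genes, had a median of -0.52 in the lnc57Rik KO library against WT. Between the lncGM1082 KO and the lnc57Rik KO library its median was 0.16, within the random lists. A heat shock response of the cells or of their handling may still be the cause: chaperone genes had a median of 0.065 over 13 genes, below the bound of 0.1 by less than their spread of 0.0615. The same genes had a median of 0.34 in the lnc57Rik KO library, where Hspa1a was lower (-1.21), so they did not follow Hspa1a there.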
